A study of Ovis aries with 22 samples.

How the data were processed

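Gene expression in the heart septum of sheep (Ovis aries) was measured on Agilent one-colour (Cy3) arrays with 15208 spots each. Per the labels' protocols, RNA was extracted with Trizol, purified on RNeasy columns with DNase digestion, and labelled from 500 ng with a One-Color Quick Amp kit. Groups came from the labels, with 6 fetuses at 130 days of gestation, 8 fetuses at term and 8 lambs aged 14 days.

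The authors deposited the scanner output of each array, whose intensity values come from Agilent Feature Extraction 10.1.1.1, per the file headers. The processed signal used here is, per the file headers, an intensity after background subtraction and detrending, not scaled between arrays. Spot flags for signal well above background, non-uniformity, outlying replicate spots and saturation are also as the deposited files give them. The authors also deposited a table of log2 values for 10089 probes, and limma is named in the submitters' processing notes without a version. These log2 values lay closest to quantile-normalised log2 median spot signal, with a mean absolute difference of 0.0449 and a lowest correlation of 0.989, so the scale and the step between arrays were inferred from the values. Column medians of that deposited table ran from 8.75 to 8.83, and the values are not centred per gene. Nothing about scale, centring or direction stayed unknown beyond what that inference leaves open, since a one-colour value has no ratio to turn.

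For this work, the log2 of the processed signal had its array's 75th percentile subtracted. Control spots and spots flagged as outliers (2 to 18 per array) were left out, spots of 1 probe were averaged, and 0 spots were saturated. Probes were named from the files' own symbols and from a RefSeq table of the Rambouillet sheep assembly, used for names alone, in which 726 of 750 RefSeq accessions on the array were found. Of 15008 probes, 1545 (10.3%) carried 1 gene symbol and 13463 did not, and 14 with several symbols were left unnamed. Gene names are therefore those of a minority of the array, and no genome position is given. A gene was represented by the probe with the highest mean signal, leaving 14347 features. Other probes of called genes changed with the same sign in 55 of 61 cases (90.2%) for term against 130 days, 212 of 270 (78.5%) for lamb against term and 201 of 246 (81.7%) for lamb against 130 days. Features well above background on a share of at least 0.5 of the arrays in 1 or more groups were tested, which left 12244.

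Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 22 arrays in 1 fit, 19 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over all features and a threshold of adjusted p under 0.05. Tables were read with data.table version 1.17.8 and figures drawn with Python 3.11.15 and matplotlib 3.10.9. The comparisons were term against 130 days, lamb against term, lamb against 130 days, and the difference between the first 2 of these. Gene lists, 25 of pathways and 10 of cell type markers, were written before the data were examined, as were the groups, the tests and most alternatives. The 17 lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Of the 8 camera calls, 7 for term against 130 days and 1 for lamb against 130 days, 0 held with a correlation estimated per list, and fry called 8, 8 and 3 lists in the 3 comparisons. For the immediate early list at term against 130 days, camera pointed up (adjusted p = 0.913) while the mean (-0.18), the median (-0.07) and fry pointed down.

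Genes could be named by a rule fixed in advance. It took the 8 largest rises and 8 largest falls among called genes with a symbol that were well above background on that share of the arrays of both groups, up to 3 bounded changes in each direction, the 2 largest called changes in each direction of each list or, with none called, the member with the smallest p, and a fixed panel of heart genes. For the difference between intervals it took 5 genes in each direction. Not every gene the rule allows is named, 1 that it allows is not reported here, and some called genes were passed over after their calls had been seen to end under other settings. IRF1, FCER1G, ITGB2, CD14 and CD3D lie outside the rule and were chosen after their values were seen. A fold written as at least a value sets the bright group's mean against, per dim array, the higher of the lowest signal well above background and the probe's own.

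The procedure was tested on simulated data built from these arrays with known changes. Changes of 1 on the log2 scale were recovered in 76.9% of genes for term against 130 days, 75% for lamb against term and 72.6% for lamb against 130 days, and changes of 0.5 in 19.7%, 24.7% and 25.9%, over 12244 genes. Of the simulated calls, 7.1%, 5.3% and 8.2% were false. The simulated noise was normal, independent between genes and of the same spread in every group, with no effect of slide or scan date. Far fewer genes were changed than the real comparisons called. The shares recovered and false therefore need not carry over to the real comparisons. Alternatives covered normexp background correction, quantile normalisation, another percentile, filters, flagged spots, probe averaging, samples in the fit, an intensity trend, array weights, slide, scan date and replicate blocks, the authors' processed values and each array left out. The normexp setting used mean spot signal and median background with an offset of 50, in place of the processed signal. A change with normexp is therefore not one of background correction alone. Lambs of 1 slide left out, a correction for probe GC content and a fit of slides 1 to 3 alone were added after the data were seen. The labels give no sex. The p-values and SEs rest on the spread between arrays within groups, pooled over all 3 groups. Tests between the fetal groups therefore also carry the larger spread of the lambs, which lay on slides scanned on separate dates. The mean SD from the group mean was 0.567 for lambs, 0.362 at 130 days and 0.391 at term.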

Results

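RNA from the septum of the sheep heart, the muscular wall between the ventricles, was measured on 22 one-colour arrays. Fetuses at 130 days of gestation gave 6 arrays, fetuses at term gave 8, and naturally born lambs aged 14 days gave 8. The labels state that neither ewe nor fetus was treated, and they do not say whether any fetuses shared a ewe. The design follows the septum over the last weeks before birth and across birth. Spots well above background numbered 10193 to 13061 of the 15208 read on an array, no spot was saturated, and the number of arrays limits the precision of what follows. After filtering, 12244 genes or unnamed transcripts were tested, 789 of them with a gene symbol. Values are log2 signal relative to the array's 75th percentile.

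The lamb arrays stood apart from the fetal arrays on the first principal component, which held 38.1% of the variance. Lambs lay between -86.4 and -21.7 on it, fetuses at 130 days between 19.2 and 34.2, and term fetuses between 23.5 and 42.3. All 14 fetal arrays were scanned on 1 date, with both fetal ages on slides 1, 2 and 3. The lambs occupied slides 5, 6 and 7, each scanned on a date of its own, so no slide or scan date held both lambs and fetuses. The lamb arrays also differed in the spike-in control spots, RNAs added in known amounts. Their mean log2 signal was 6.32 to 6.55 at 130 days, 6.35 to 7.25 at term and 8.24 to 10.02 in lambs.

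**Figure D1:**
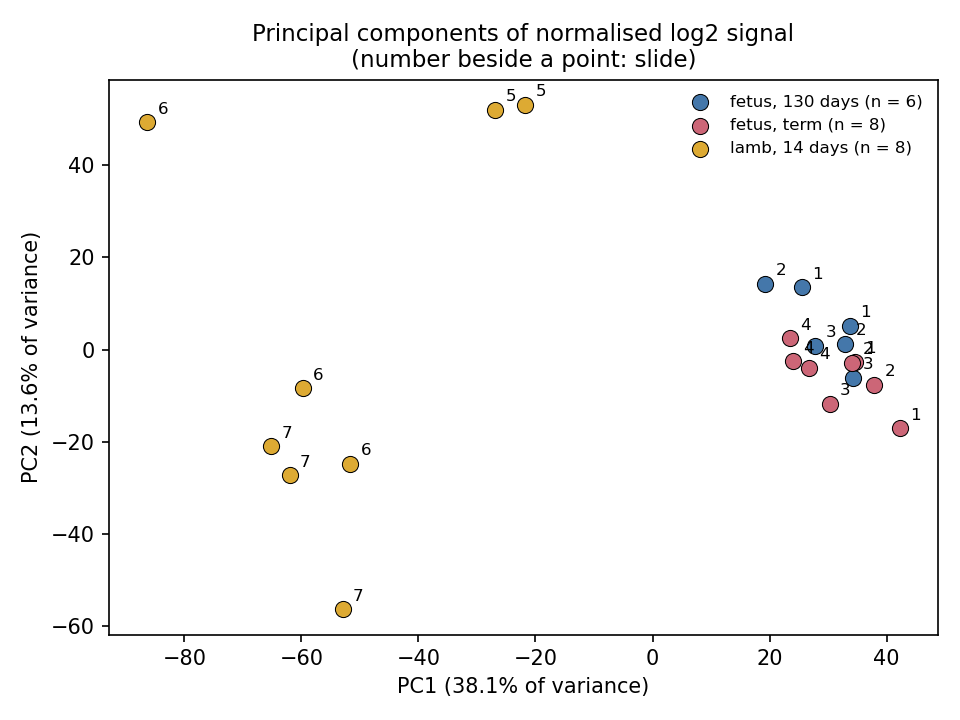
First (x axis) and second (y axis) principal component of the normalised log2 signal, in component units, with 1 point per array coloured by group and numbered by slide. The 8 lamb arrays lie at -86.4 to -21.7 on the first component and the 14 fetal arrays at 19.2 to 42.3.

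The first comparison asked what changed in the septum between 130 days of gestation and term. The lists of interferon-response genes and leukocyte markers were lower at term as sets, and those of fatty acid uptake and oxidation and of oxidative phosphorylation were higher, all at camera's preset correlation. In that order, adjusted p = 0.226, 0.207, 0.242 and 0.308 with an estimated correlation, which ended all 4 calls, and 6 of 100 splits of the arrays, the real one included, called as many lists. CXCL10, a chemokine induced by interferon, was 22.5-fold lower (log2 change -4.49 ± 0.84 SE, limma adjusted p = 0.0028, n = 8 against 6). It was -3.73 without 130-day fetus 3 and -2.80 with normexp background correction, and stayed called in both. ISG15, an interferon-induced ubiquitin-like protein, was 8.07-fold lower (-3.01 ± 0.76, adjusted p = 0.0166). GLUT4, the insulin-responsive glucose transporter, was 2.34-fold higher (1.23 ± 0.19, adjusted p = 0.000919). In all, 1121 genes passed adjusted p under 0.05, 519 higher and 602 lower at term, and 97 of them carried a symbol. Of the 299 genes that changed by more than 2-fold, 62 were higher and 237 lower.

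All 7 measured interferon-response genes were lower at term when adjusted over the list alone, and 4 passed over all genes (camera adjusted p = 5.07e-05, and adjusted p = 0.226 with an estimated correlation). They were CXCL10, ISG15, MX1, an antiviral GTPase (-2.06 ± 0.56, adjusted p = 0.0246), and the transcription factor IRF1 (-1.66 ± 0.36, adjusted p = 0.00789). IRF1, FCER1G, ITGB2, CD14 and CD3D were named after their values had been seen. Of 11 measured leukocyte markers, 5 were lower over all genes and 5 adjusted over the list alone (camera adjusted p = 6.44e-05, and adjusted p = 0.207 with an estimated correlation). These were FCGR1A, a high-affinity receptor for IgG (-1.91 ± 0.40, adjusted p = 0.00505), the lysosomal protease CTSS (-1.37 ± 0.29, adjusted p = 0.0069), lysozyme LYZ (-1.41 ± 0.39, adjusted p = 0.0255), the Fc receptor gamma chain FCER1G (-1.16 ± 0.26, adjusted p = 0.00925) and the integrin ITGB2 (-1.02 ± 0.23, adjusted p = 0.00896). The monocyte marker CD14 (-0.10, adjusted p = 0.783) and the T cell marker CD3D (-0.44, adjusted p = 0.43) did not pass. Signals of 130-day fetus 3 were the highest of their group for CXCL10, ISG15, FCGR1A, MX1, CTSS, FCER1G and CLEC6A. Without it FCGR1A stayed called (-1.44, adjusted p = 0.00743). Also without that array the calls of ISG15 (-2.46, adjusted p = 0.0537), MX1 (-1.59, adjusted p = 0.0791) and LYZ (-1.11, adjusted p = 0.0823) ended, as did that of MX1 without term fetus 1 (-1.85, adjusted p = 0.0507) and that of LYZ without 130-day fetus 4 (-1.22, adjusted p = 0.0713). CLEC6A, a C-type lectin of myeloid cells, fell by 1.96 and lost its call when any of 9 single arrays was left out (highest adjusted p = 0.0747, without 130-day fetus 3). The cytokine IL1A was well above background on 5 of 6 arrays at 130 days and on none at term, which made it at least 2.27-fold lower (adjusted p = 0.0246), but with normexp background correction its change was 0.23 (adjusted p = 0.687).

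Several genes outside these lists were also lower at term. IGFBP2, a binding protein for insulin-like growth factors, fell by 1.84 ± 0.47 (adjusted p = 0.0166), and INHBA, the beta A subunit of activin and inhibin, fell by 2.00 ± 0.38 (adjusted p = 0.00303). The list of insulin-like growth factor and insulin signalling had 1 of 11 measured genes lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.266). The fetal growth factor IGF2 had a change of -1.07 ± 0.37 that did not pass (adjusted p = 0.0754), with term fetus 1 at 3.03 and the next lowest term array at 5.89. AHSP, the chaperone of alpha haemoglobin and the measured member of the erythroid list, fell by 2.93 ± 0.65 (adjusted p = 0.0085) and was -0.87 with normexp. The 6 measured genes of cell cycle and DNA replication were lower as a set (camera adjusted p = 0.00812, and adjusted p = 0.332 with an estimated correlation), but 1 passed singly, over all genes and over the list alone. That gene was TYMS, which makes thymidylate for DNA (-1.49 ± 0.46, adjusted p = 0.0419), and its call ended when any of 12 single arrays was left out (highest adjusted p = 0.11, without 130-day fetus 1). The mitotic kinase CDK1 had a change of -1.11 ± 0.56 (adjusted p = 0.225). None of 5 measured fibroblast markers passed over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.0412, and adjusted p = 0.242 with an estimated correlation), and none of 13 extracellular matrix genes passed in limma by either adjustment (camera adjusted p = 0.103). Under other settings DCN and COL3A1, members of both lists, passed over all genes in 10 and 2 of 41 alternatives.

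Of 6 measured genes of fatty acid uptake and oxidation, 3 were higher at term by both adjustments (camera adjusted p = 0.0156, and adjusted p = 0.242 with an estimated correlation). LPL, which releases fatty acids from circulating lipoproteins, rose 1.71-fold (0.77 ± 0.19, adjusted p = 0.0134), CPT1B, the muscle form of the enzyme that passes fatty acids into mitochondria, rose 1.57-fold (0.66 ± 0.14, adjusted p = 0.00731), and the lipid droplet protein PLIN5 rose 1.98-fold (0.98 ± 0.29, adjusted p = 0.0361). CPT1A, the liver form, differed by 0.44 ± 0.39 (adjusted p = 0.539). The 6 measured genes of oxidative phosphorylation were higher as a set (camera adjusted p = 0.00711, and adjusted p = 0.308 with an estimated correlation), with 0 passing over all genes in limma, where the list's smallest adjusted p was 0.0536 for ATP5PO, and 3 adjusted over the list alone. In 15 of 41 alternatives ATP5PO did pass over all genes. Of 8 adipocyte markers, 2 were higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00732, and adjusted p = 0.207 with an estimated correlation). LPL belongs to that list too. Of 7 genes of glycolysis and glucose uptake, 2 were higher by both adjustments (camera adjusted p = 0.0704), the glycolytic enzymes ENO3 (0.67 ± 0.14, adjusted p = 0.0063) and ALDOA (0.52 ± 0.13, adjusted p = 0.0153). The list also names SLC2A4, another symbol of GLUT4, which the matching of symbols missed. Neither the 7 genes nor the list test therefore include GLUT4, although it was measured and called higher (1.23). HSD11B1, which regenerates active glucocorticoid, rose 1.93-fold (0.95 ± 0.27, adjusted p = 0.0266). The hormone signalling list that holds it had 2 of 13 genes higher by both adjustments (camera adjusted p = 0.266). The glucocorticoid receptor NR3C1 (0.20 ± 0.37, adjusted p = 0.796) and HSD11B2, which inactivates glucocorticoid (1.44 ± 0.60, adjusted p = 0.137), did not pass. Other large rises were ITGB6, an integrin subunit (1.89 ± 0.49, adjusted p = 0.0177), the tubulin TUBA4A (1.82 ± 0.30, adjusted p = 0.00136), ALDH1A1, which makes retinoic acid (1.53 ± 0.30, adjusted p = 0.00378), SLC25A33, a mitochondrial pyrimidine carrier (1.26 ± 0.18, adjusted p = 0.000453), and ACSS2, which makes acetyl-CoA from acetate (0.96 ± 0.27, adjusted p = 0.0293).

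For each gene named here as lower at term, all 8 term arrays lay below the 130-day mean. For each gene named as higher, all 8 lay above it, except 7 of 8 for ITGB6. Slides 1, 2 and 3 held both ages. With slide as a block, in a fit of the fetal arrays alone, 2244 genes passed, 1006 of the 1121 among them, and 57.1% were higher at term. The fetal groups alone without the block gave 2420 genes, 52.8% of them higher, against 46.3% of the 1121 with all arrays fitted. The rise from 1121 thus came with the lambs left out of the fit, not with the block. Within slides 1, 2 and 3 the mean shift against other genes was -2.22, -2.85 and -1.70 for the interferon list, -0.90, -1.42 and -0.50 for leukocytes, -0.43, -1.18 and -1.59 for the cell cycle, 0.53, 0.54 and 0.36 for fatty acids, 0.65, 0.60 and 0.67 for oxidative phosphorylation, and 0.21, 0.50 and 0.69 for adipocytes. The fibroblast shift was -0.61, -0.50 and 0.04, so it was absent from slide 3. With the block these shifts were -2.32, -0.99, -1, 0.49, 0.64, 0.39 and -0.41 in the same order, and camera adjusted p rose to 0.106 for the fatty acid list and 0.0537 for the fibroblast list, which ended both calls.

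The count ran from 644 without 130-day fetus 3 to 1406 without lamb 8, was 671 and 723 without 130-day fetuses 1 and 4, and with normexp was 460, where the calls of AHSP, CLEC6A, FCGR1A, IL1A, TYMS, LYZ, ITGB2, ACSS2 and ALDOA ended. Slide as a block ended the calls of CLEC6A, TYMS and ITGB6, the authors' processed values those of CLEC6A and ENO3, and a fit of slides 1 to 3 alone those of CLEC6A, TYMS, ITGB6, IL1A, LPL and PLIN5. With the replicate number as a block the fit ended those of LPL (0.74, adjusted p = 0.0678), HSD11B1 (0.93, adjusted p = 0.0623), LYZ (adjusted p = 0.0755), ITGB6 (adjusted p = 0.0853), CLEC6A (adjusted p = 0.101) and TYMS (adjusted p = 0.0755), the mean of all probes of a gene ended that of CLEC6A (adjusted p = 0.0505), and keeping dim probes ended that of TYMS (adjusted p = 0.052). Leaving out 1 array, beyond the cases above, ended those of ITGB6 (2 arrays, highest adjusted p = 0.0537 without 130-day fetus 1), PLIN5 (9, 0.09 without 130-day fetus 1), ACSS2 (5, 0.0688 without 130-day fetus 5), HSD11B1 (4, 0.0661 without 130-day fetus 6) and IL1A (2, 0.0719 without 130-day fetus 3). Over all alternatives the changes ran from -2.31 to -0.45 for FCGR1A (lowest in size with normexp, adjusted p = 0.469), -1.86 to -0.99 for IRF1, -1.76 to -0.57 for LYZ, -2.31 to -0.72 for CLEC6A, -4.00 to -0.87 for AHSP, -1.95 to -0.90 for TYMS and -5.16 to -2.80 for CXCL10.

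**Figure D2:**
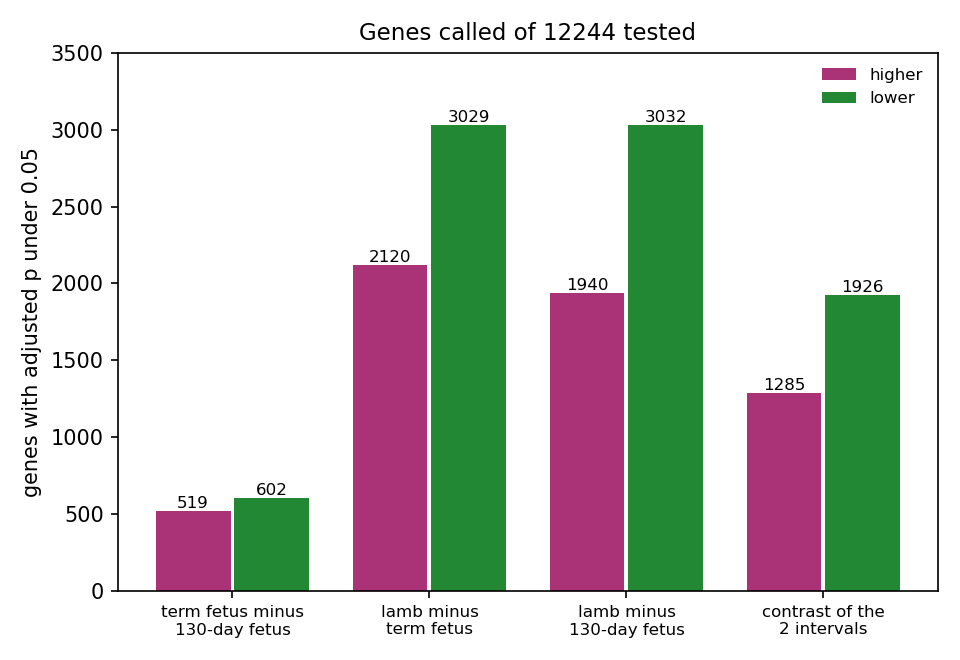
Bars give the number of genes (y axis, from 0) with limma adjusted p under 0.05, higher and lower, for each comparison (x axis), of 12244 tested. Between 130 days and term 519 were higher and 602 lower, and between term and lamb 2120 were higher and 3029 lower, a split that turned to 58.3% higher with normexp background correction and 52.3% with quantile normalisation.

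The second comparison asked what changed across birth, from term fetus to the lamb of 14 days. The Fc receptor gene FCGR1A, the growth factor gene IGF1, the growth hormone receptor gene GHR and the fatty acid enzyme CPT1A were higher in lambs, and 3 cathelicidin genes, CALCA, PRLH and the muscle genes MYL11 and TNNC2 were lower. The calls of FCGR1A, IGF1, GHR, CPT1A, TNNC2 and the 3 cathelicidin genes ended with scan date as a random block, while those of CALCA, PRLH and MYL11 held. No list passed as a set. FCGR1A was 5.07-fold higher (2.34 ± 0.37, adjusted p = 2.72e-05) and CPT1A 2.84-fold higher (1.5 ± 0.36, adjusted p = 0.00195, n = 8 against 8). PRLH, a prolactin-releasing peptide, was 32.3-fold lower (-5.01 ± 0.23, adjusted p = 3.81e-12), and CATHL1B, an antimicrobial peptide of the cathelicidin family, was 21-fold lower (-4.40 ± 0.81, adjusted p = 0.000158), but -1.53 with normexp. In all, 5149 genes passed, 2120 higher and 3029 lower, and 378 carried a symbol. With scan date as a random block 977 passed, 97 higher and 880 lower, because every lamb was scanned on another date than every fetus. Among lambs, which share 1 age, 1797 genes differed between slides 5 and 7, 301 between slides 5 and 6, and 0 by limma between slides 6 and 7 (1803 at an unadjusted p under 0.05).

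Of 7 interferon-response genes, 6 were higher in lambs by both adjustments, among them CXCL10 (2.15 ± 0.78, adjusted p = 0.0298) and ISG15 (2.08 ± 0.71, adjusted p = 0.0219, higher in 7 of 8 lambs), while the list as a set did not pass (camera adjusted p = 0.0574). The call of CXCL10 ended when any of 5 arrays was left out (highest adjusted p = 0.0683, without term fetus 2), with array weights (1.64, adjusted p = 0.11) and with the authors' processed values (1.14, adjusted p = 0.103), and that of ISG15 ended without term fetus 2 (1.70, adjusted p = 0.0507). Of 11 leukocyte markers, 4 were higher and 1 lower over all genes, and 6 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.247). They included FCGR1A and CTSS (1.67 ± 0.27, adjusted p = 4.69e-05). The class II histocompatibility gene MHCII-DRB1 rose 3.46-fold (1.79 ± 0.41, adjusted p = 0.00141), the cytokine IL18 rose 3.29-fold (1.72 ± 0.25, adjusted p = 1.08e-05), and OVAR rose 4.93-fold (2.30 ± 0.41, adjusted p = 0.000108). PGR, the progesterone receptor, rose 5.8-fold (2.54 ± 0.68, adjusted p = 0.00457).

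Of 11 genes of insulin-like growth factor and insulin signalling, 4 were higher and 2 lower by both adjustments (camera adjusted p = 0.356). IGF1 rose 2.33-fold (1.22 ± 0.30, adjusted p = 0.00243, higher in 7 of 8 lambs), the growth hormone receptor GHR rose 1.91-fold (0.93 ± 0.22, adjusted p = 0.00162), and the binding protein IGFBP5 fell by 1.12 ± 0.22 (adjusted p = 0.000256). IGF2 (-0.63 ± 0.34, adjusted p = 0.147) did not pass. Of 6 fatty acid genes, 3 were higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.247), including LPL (0.54 ± 0.17, adjusted p = 0.0159). Of 6 genes of oxidative phosphorylation, 3 were lower by both adjustments (camera adjusted p = 0.448), among them the ATP synthase subunit ATP5PO (-0.50 ± 0.16, adjusted p = 0.0156, lower in 7 of 8 lambs). Among 6 endothelial markers 2 were higher by both adjustments (camera adjusted p = 0.247), the vascular endothelial growth factor receptor KDR (1.45 ± 0.17, adjusted p = 8.47e-07) and the adhesion molecule PECAM1 (0.68 ± 0.20, adjusted p = 0.0107, higher in 7 of 8 lambs). Of 5 fibroblast markers 2 were higher by both adjustments (camera adjusted p = 0.38), the collagen COL3A1 (0.76 ± 0.20, adjusted p = 0.00346) and the filament protein VIM (0.72 ± 0.24, adjusted p = 0.0197), each in 7 of 8 lambs. Among 13 matrix genes 3 were higher and 1 lower by both adjustments (camera adjusted p = 0.511), with the protease inhibitor TIMP1 at 0.81 ± 0.23 (adjusted p = 0.00812).

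The largest falls held 3 cathelicidin genes, CATHL1B, CATHL3 (-3.96 ± 0.94, adjusted p = 0.00185) and BAC5 (-3.67 ± 0.83, adjusted p = 0.00116), which were well above background on all 8 term arrays and on 4, 4 and 5 lamb arrays, and whose changes with normexp were -1.53, -1.40 and -1.54. CALCA, which encodes calcitonin and calcitonin gene-related peptide, fell by 4.89 ± 0.30 (adjusted p = 2.17e-09), with 6 term values left after flagged spots were dropped. Genes of fast skeletal fibres fell too, namely the myosin light chain MYL11 (-4.00 ± 0.26, adjusted p = 5.88e-10) and troponin TNNC2 (-3.39 ± 0.68, adjusted p = 0.000398). ZFP36, which speeds the decay of cytokine messages, fell by 2.17 ± 0.15 (adjusted p = 9.78e-10), although another probe of the gene changed by 0.17. EGR1, an immediate early transcription factor, fell by 0.78 ± 0.14 (adjusted p = 0.000145), although another of its probes changed by 1.87 and the mean of its probes by 0.54 (adjusted p = 0.127). The immediate early list had 2 of 6 genes lower by both adjustments (camera adjusted p = 0.549). Of 13 hormone signalling genes, 1 was higher and 4 lower by both adjustments (camera adjusted p = 0.605), with the beta-3 adrenergic receptor ADRB3 lower (-1.47 ± 0.22, adjusted p = 1.52e-05) and the thyroid hormone receptor THRB higher (0.50 ± 0.12, adjusted p = 0.00214). Among 8 adipocyte markers 1 was higher and 3 lower by both adjustments (camera adjusted p = 0.38), with the lipid droplet coat protein PLIN1 at -1.45 ± 0.17 (adjusted p = 7.16e-07). Of 5 antioxidant genes 1 was higher and 2 lower by both adjustments (camera adjusted p = 0.511), the latter being GLRX2 (-1.33 ± 0.24, adjusted p = 0.000138) and GSTA1 (-1.30 ± 0.18, adjusted p = 7.93e-06). The pigment-signalling gene ASIP was at -4.70 in lamb 3 and -5.51 in lamb 8 and between 4.08 and 5.68 on the other 20 arrays, and its call (adjusted p = 0.043) ended without lamb 3 (-2.28, adjusted p = 0.0905) and without lamb 8 (-2.17, adjusted p = 0.0748), among 10 such arrays. It also ended with quantile normalisation (adjusted p = 0.0568), with dim probes kept (0.0517), with the 2 groups alone (0.0854) and without the lambs of slide 6 (0.0508) or 7 (0.0743).

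Where no other count is given, every lamb lay on the named side of the term mean for the genes named as changed. No list passed camera in this comparison (0 of 17, 3 at an unadjusted p under 0.05), whereas fry, which tests whether a list's genes move one way on balance, called 8. With scan date as a random block the calls of CATHL1B, CATHL3, BAC5, TNNC2, PGR, FCGR1A, OVAR, CXCL10, ISG15, MHCII-DRB1, CTSS, CPT1A, LPL, PECAM1, COL3A1, TIMP1, VIM, IGF1, GHR, IGFBP5, EGR1, THRB, ATP5PO and ASIP ended, while those of PRLH, CALCA, MYL11, IL18, KDR, ZFP36, ADRB3, PLIN1, GLRX2 and GSTA1 held. The changes themselves hardly moved, with FCGR1A at 2.33, CPT1A at 1.48 and CATHL1B at -4.54. With normexp 2835 genes passed and the calls of CATHL3, CXCL10, LPL, VIM, EGR1 and ADRB3 ended, those of LPL, PECAM1 and VIM ended without the lambs of slide 7, those of CXCL10, ISG15 and ATP5PO ended without the lambs of slide 6, that of ATP5PO also without slide 5, and slide as a block ended those of CXCL10, ISG15, LPL, VIM and ASIP. Over all alternatives the changes ran from 1.05 to 2.62 for FCGR1A, 1.08 to 2.89 for PGR, 1.14 to 2.48 for CXCL10, 0.83 to 1.98 for IL18, -5.24 to -4.33 for PRLH, -5.08 to -3.40 for CALCA, -4.28 to -2.50 for TNNC2, -1.80 to -0.33 for ADRB3, -1.55 to -0.84 for PLIN1 and -2.23 to -1 for ZFP36. For CATHL1B, CATHL3 and BAC5 they ran from -5.18, -5.20 and -4.73 to the values with normexp.

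**Figure D3:**
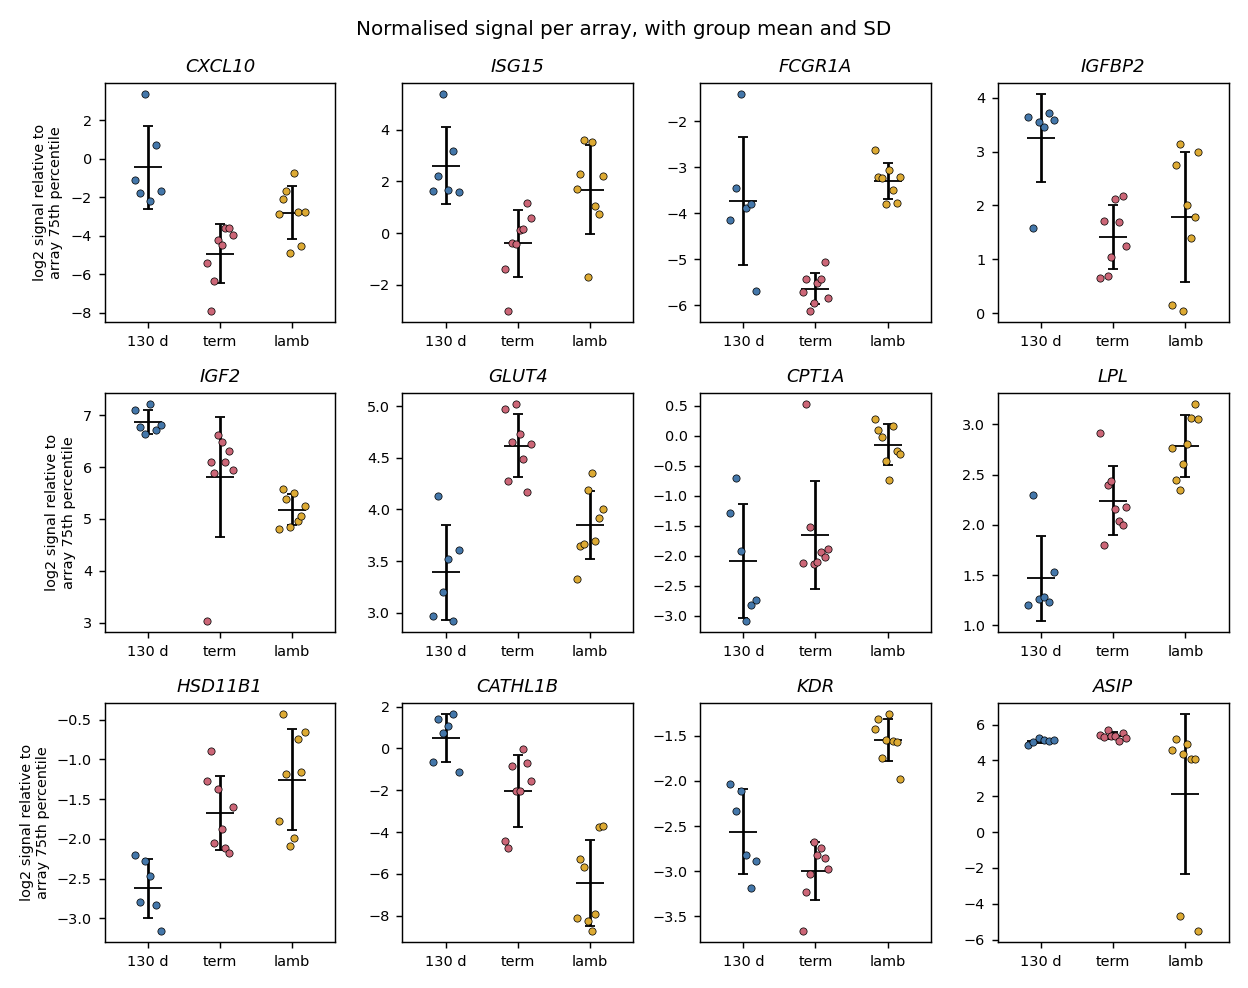
Normalised log2 signal relative to the array's 75th percentile (y axis, its own range in each panel) for 12 genes in the 130-day, term and lamb groups (x axis), with 1 point per array and black bars for the group mean and SD. CXCL10 averages -0.45 at 130 days, -4.94 at term and -2.79 in lambs, LPL rises from 1.47 through 2.24 to 2.79, and ASIP is at -4.70 and -5.51 in 2 lambs and at 4.08 or more on the other 20 arrays.

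The third comparison spanned the whole period, from 130 days of gestation to the lamb. Of 6 measured fatty acid genes 4 were higher in lambs (adjusted p = 0.589 for the list with an estimated correlation), and the cathelicidin genes, IGF2 and its binding protein IGFBP2 were lower. CPT1A rose 3.85-fold (1.94 ± 0.39, adjusted p = 0.000428), LPL 2.49-fold (1.32 ± 0.19, adjusted p = 1.49e-05) and CPT1B 1.88-fold (0.91 ± 0.14, adjusted p = 3.81e-05, n = 8 against 6). CATHL1B, well above background on 4 of 8 lamb arrays, was 123-fold lower (-6.95 ± 0.87, adjusted p = 3.55e-06, but -3.60 with normexp), and IGF2 was 3.25-fold lower (-1.70 ± 0.37, adjusted p = 0.000971). In all, 4972 genes passed, 1940 higher and 3032 lower, and 347 carried a symbol. The higher share was 39%, against 73.7% with normexp, 52.5% with quantile normalisation and 50.4% with the authors' values. With scan date as a random block 946 passed, where the calls of CPT1A, IGF2 and IGFBP2 ended and those of LPL, CPT1B and the cathelicidins held.

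Of 6 fatty acid genes, 4 were higher by both adjustments (camera adjusted p = 0.00855, and adjusted p = 0.589 with an estimated correlation), and this was the 1 list of 17 that passed. FABP5, a fatty acid binding protein, rose 3.19-fold (1.67 ± 0.23, adjusted p = 1.01e-05) and ACSS2 rose 5-fold (2.32 ± 0.27, adjusted p = 1.89e-06). The adipocyte regulator PPARG rose 1.92-fold (0.94 ± 0.27, adjusted p = 0.00755), with 2 markers of that list higher and 3 lower by both adjustments (camera adjusted p = 0.985). Of 11 insulin-like growth factor genes 3 were higher and 4 lower by both adjustments (camera adjusted p = 0.974). Among them GHR rose 2.28-fold (1.19 ± 0.24, adjusted p = 0.000386), IGFBP2 fell by 1.47 ± 0.47 (adjusted p = 0.015), and IGF1 (0.65 ± 0.32, adjusted p = 0.114) did not pass. CDKN1C, an imprinted inhibitor of the cell cycle, fell by 0.70 ± 0.16 (adjusted p = 0.0011). HSD11B1 rose 2.58-fold (1.37 ± 0.27, adjusted p = 0.000317), and HSD11B2 (0.95 ± 0.60, adjusted p = 0.218) and NR3C1 (-0.17 ± 0.37, adjusted p = 0.74) did not pass. SOD2, the mitochondrial superoxide dismutase, rose 2.38-fold (1.25 ± 0.25, adjusted p = 0.000394). ITGB6 rose 8.91-fold (3.15 ± 0.49, adjusted p = 3.19e-05), ALDH1A1 rose 5.44-fold (2.44 ± 0.30, adjusted p = 2.9e-06), and ABCB1, a drug efflux pump, rose 4.07-fold in 7 of 8 lambs (2.02 ± 0.59, adjusted p = 0.00904).

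Among endothelial markers 3 of 6 were higher by both adjustments (camera adjusted p = 0.448), with KDR at 1.01 ± 0.18 (adjusted p = 0.000156). COL4A3, a basement membrane collagen, was not well above background at 130 days and was at least 4.84-fold higher in lambs (adjusted p = 0.000668), a bound taken from the processed signal, and its change of 2.62 was 1.31 with normexp and 0.58 with the authors' values. The other cathelicidins were also lower, CATHL3 by 72.6-fold (-6.18 ± 1.02, adjusted p = 6.3e-05), BAC5 by 51.7-fold (-5.69 ± 0.89, adjusted p = 3.83e-05) and SC5 by 8.13-fold (-3.02 ± 0.37, adjusted p = 2.4e-06). With normexp these were -3.09, -3.14 and -1.36, and CATHL3 and BAC5 were well above background on 4 and 5 of 8 lamb arrays. Lactoferrin, LTF, was not well above background in any lamb and was at least 4.49-fold lower (adjusted p = 0.000812), but its change was 0.31 with normexp. AHSP, well above background on 2 of 8 lamb arrays, fell by 4.59 ± 0.65 (adjusted p = 1.4e-05) and was -0.77 with normexp (adjusted p = 0.105). Of 6 cell cycle genes 1 was lower by both adjustments (camera adjusted p = 0.576), the mitotic kinase AURKA (-1.41 ± 0.34, adjusted p = 0.0022). Of 7 interferon genes 1, CXCL10, was lower over all genes (-2.34 ± 0.84, adjusted p = 0.0295) and 0 adjusted over the list alone (camera adjusted p = 0.985), and of 11 leukocyte markers 2 were lower over all genes and 1 adjusted over the list alone (camera adjusted p = 0.974).

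Every lamb lay on the named side of the 130-day mean for the genes named as changed, ABCB1 apart. Scan date as a random block ended the calls of ITGB6, ABCB1, CPT1A, LTF, COL4A3, HSD11B1, IGF2, GHR, SOD2, KDR, CXCL10, IGFBP2, AURKA, PPARG and CDKN1C and kept those of the cathelicidins, LPL, CPT1B, FABP5, ACSS2, ALDH1A1 and AHSP. The changes themselves hardly moved, with ITGB6 at 3.12, IGF2 at -1.70 and KDR at 1.02. The calls of AHSP, LTF and AURKA ended with normexp, those of IGFBP2 and CDKN1C with a correction for probe GC content, that of ABCB1 without the lambs of slide 6, those of PPARG and CXCL10 without slide 7, and that of CXCL10 also with slide as a block and when any of 4 arrays was left out (highest adjusted p = 0.0988, without 130-day fetus 3). Over all alternatives the changes ran from 2.43 to 3.56 for ITGB6, 1.25 to 2.73 for ABCB1, -1.65 to -0.17 for AURKA, -2.70 to -1.55 for CXCL10, and from -7.73 for CATHL1B, -7.42 for CATHL3 and -6.76 for BAC5 to the values with normexp.

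A last comparison asked which genes changed differently after term than before it. CXCL10, ISG15 and FCGR1A had fallen before term and were higher again in lambs. The contrast was 6.64 ± 1.38 for CXCL10 (adjusted p = 0.00155), 5.09 ± 1.26 for ISG15 (adjusted p = 0.00523), 4.25 ± 0.65 for FCGR1A (adjusted p = 0.000101), 3.51 ± 0.73 for MHCII-DRB1 (adjusted p = 0.00162) and 3.50 ± 0.73 for OVAR (adjusted p = 0.00154). At the other end stood CALCA (-5.38 ± 0.57, adjusted p = 8.28e-06), PRLH (-5.25 ± 0.42, adjusted p = 1.85e-07), MYL11 (-4.44 ± 0.47, adjusted p = 2.95e-06), TNNC2 (-3.91 ± 1.21, adjusted p = 0.0213) and EM4B (-3.42 ± 0.56, adjusted p = 0.000199). In all, 3211 genes passed, 1285 above 0 and 1926 below, and 1190 did with scan date as a random block, where TNNC2 and ISG15 did not. Normexp left 1135 genes and ended the calls of EM4B and FCGR1A, and TNNC2 did not pass without the lambs of slide 7. Over all alternatives the contrast ran from 4.04 to 7.03 for CXCL10, 4.20 to 5.58 for ISG15, 1.54 to 4.65 for FCGR1A, 2.84 to 3.77 for MHCII-DRB1, -5.76 to -3.89 for CALCA, -5.47 to -4.55 for PRLH, -4.80 to -3.02 for TNNC2 and -3.70 to -0.59 for EM4B.

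Genes called in both intervals numbered 532, of which 441 (82.9%) changed in opposite directions. Lower then higher were 287 genes, against 104.2 for independent lists of these sizes, and higher then lower were 154, against 128.4. Higher in both were 70 genes, against 89.9, and lower in both were 21, against 148.9. The intervals share the term arrays with opposite sign, which by itself makes changes oppose each other. In 100 simulations of unchanged groups that shared the term arrays, 0 genes were called in both by limma, and 64.9% of genes had opposite signs, against 59.8% observed. With no group change left, calls were hardly possible, so the 0 cannot show how many of the 532 come from the shared arrays. The simulated term arrays also drew on residuals of lambs, whose mean SD from the group mean was wider (0.567 against 0.391 at term). The correlation of the changes across genes, which are not independent replicates, was -0.298, against a simulated mean of -0.455. Their covariance was -0.104, against -0.028, a difference of -0.076. With the term arrays divided so that each interval used its own 4, the correlation was -0.225 or -0.224, the covariance -0.086 or -0.081, and 302 or 204 genes were called in both, 244 or 177 of them in opposite directions. These calls came from fits of the 2 groups alone, which with all term arrays gave 994 genes called in both, not from the fit that gave 532. Each interval then also had fewer term arrays, so the lower counts do not measure the effect of sharing them. The count of 532 was 125 with scan date as a random block, 176 with normexp, 307 without 130-day fetus 3 and 327 without 130-day fetus 1.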

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

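The tests of slides, scan dates, spike-in controls, probe GC content and leukocyte markers in this part were chosen after the results were seen, and the tests on pairs of 130-day arrays and on other splits of the arrays were not. In 100 splits of the same arrays, the real one included, no other split gave as many genes as the real one. The total counts were 1121 genes at term against 130 days (highest other split 65), 5149 at lamb against term (4), 4972 at lamb against 130 days (241), 3211 for the contrast of intervals (highest other 1) and 532 called in both intervals (highest other 0), with 1 split of 100 in each case as large. Random labels are thus an unlikely source of these totals, but the splits do not exclude chance for single genes. Other splits also mix the real groups, which widens the spread and lowers their counts. For lambs the splits cannot part age from slides and scan dates. For the lists chance was not excluded. As many were called in 6 of 100 splits for term against 130 days (7 real, 9 in the highest other) and in 73 for lamb against 130 days (1 real, 6 in the highest other). For lamb against term 0 lists were called by camera in the real grouping (6 in the highest other). Every split reaches a count of 0, so its 100 of 100 decides nothing. A split of the fetal arrays by slide, slides 1 and 2 against 3 and 4, gave 0 genes by limma (324 at an unadjusted p under 0.05) and 0 lists by camera.

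Spike-in controls, which the comparisons did not use, were higher on every lamb array than on every fetal array, with a gap of 0.99 on the log2 scale between the lowest lamb array and the highest fetal one, and the weighed pattern is the 5149 genes that differ between lamb and term. If labelling or hybridisation strength traced by those controls made the change, it should grow with them. The median change of the called genes in their called direction differed by -0.02 between slide 7 and slide 6, whose spike-in means were 9.82 and 8.29. On slide 5, with a spike-in mean of 8.89, the median was 0.628, against 0.821 on slide 6 and 0.804 on slide 7. The change thus did not grow with the controls among the lamb slides. The genes were called on all lambs together, which favours like changes on slides 6 and 7. The values therefore cannot exclude an effect shared by all lamb slides. A correction for probe GC content kept 93.2% of the calls in their direction, which argues against that trend as the whole cause. Slides and scan dates cannot be told apart from age, since no slide or date holds both lambs and fetuses, with scan date as a random block 977 genes passed, and among lambs alone 1797 genes differed between slides 5 and 7, 301 between 5 and 6, and 0 by limma between 6 and 7 (1803 at an unadjusted p under 0.05). A single step between the fetal and the lamb hybridisations may therefore account for part or all of the change. The 977 genes that passed with the block are not thereby shown to be free of such a step. Age itself stays open as an untested biological explanation.

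Genes whose change differed between the intervals numbered 3211 in a test of the difference itself. The interval contrasts that stood out were -5.38 for CALCA, -5.25 for PRLH, -4.44 for MYL11, -3.91 for TNNC2, -3.42 for EM4B, 3.50 for OVAR, 3.51 for MHCII-DRB1, 4.25 for FCGR1A, 5.09 for ISG15 and 6.64 for CXCL10.

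The interferon and leukocyte genes among these had fallen between 130 days and term. With each of the 15 pairs of 130-day arrays left out the interferon list stayed called at the preset correlation (camera adjusted p at most 0.00128). With an estimated correlation it was not called even with all arrays (adjusted p = 0.226), so these calls cannot decide whether the fall rests on a few arrays. The list's mean change stayed below 0, from -1.33 to -2.41, against -2.02 with all arrays. It was smallest without 130-day fetuses 3 and 5, so 1 or 2 arrays did not make the whole fall, but its size depended on them. Without 130-day fetus 3 alone the calls of ISG15 and MX1 ended, while those of CXCL10 and IRF1 held. Slides are argued against as the cause, because the smallest fall of the list within 1 slide was -1.70, with -2.22 and -2.85 on the others. Fewer leukocytes at term cannot be told apart from a lower interferon response, as 6 of 11 leukocyte markers changed by less than the median interferon gene (-1.66) with their whole 95% interval, while the leukocyte median was also lower (-0.84), and a change among myeloid cells stays open. Age, the group difference of the design, may act through either, and that was not tested.

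Single arrays stood apart from the rest of their group in 32 of 262 groups of values for 88 named genes, where chance flags about 1 in 20 groups, or 13.1. Of these, 10 fell on 130-day fetus 2, 5 on term fetus 2, 4 each on 130-day fetus 3 and term fetus 1, and 3 on lamb 8. In 130-day fetus 2 the lowest values of the group were CDK1 at -4.74, TYMS at -4.61, INHBA at -1.62, IGFBP2 at 1.59, PECAM1 at 1.25 and VIM at 6.50, and the highest were TNNC2 at 6.10, LPL at 2.30, SLC25A33 at -0.93 and PLIN5 at -2.02. In 130-day fetus 3 the highest were MX1 at 3.86, CTSS at 1.62, FCER1G at 0.36 and CLEC6A at 0.31, and in 130-day fetus 4 DCN was highest at 5.99. In term fetus 2 the lowest were MHCII-DRB1 at -3.62, COL3A1 at -2.58 and FGF1 at 2.55, and the highest were CPT1A at 0.54 and FABP5 at 4.62. Term fetus 1 was lowest for IGF2 at 3.03, IGF1R at -1.89 and TIMP1 at 1.46 and highest for PLIN1 at -0.48. HSD11B2 was highest in term fetus 3 at -0.12, and NPY was lowest in term fetus 5 at -2.48. Lamb 8 was lowest for ABCB1 at -6.65, IRF1 at -3.75 and ENO3 at 3.42. The remaining lows were GSTA1 in lamb 1 at -2.13, IGF1 in lamb 4 at -4.18 and LYZ in lamb 7 at -4.52.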

How the results depend on the processing

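The lambs of 1 slide left out, the probe GC correction and the list counts with single arrays left out were chosen after the data were seen. Of 125 calls of selected genes, 121 held with quantile normalisation, 113 with slide as a block, 91 with normexp, 69 with scan date as a random block and, of 123, 114 with the authors' processed values, and all 125 held with an intensity trend and with outlying spots kept. The selected genes do not stand for all called genes. Of all 1121 called for term against 130 days, 979 stayed called with quantile normalisation, 448 with normexp and 812 with the authors' values. Of 5149 for lamb against term these were 4588, 2694 and 3454, and of 4972 for lamb against 130 days 4125, 2769 and 3110. The median change of all tested genes was 0.15 with normexp against -0.007 for term against 130 days, 0.199 against -0.018 for lamb against term and 0.305 against -0.076 for lamb against 130 days. The higher share of calls went from 41.2% to 58.3% with it for lamb against term (52.3% with quantile normalisation, 51.4% with the authors' values) and from 39% to 73.7% for lamb against 130 days (52.5% and 50.4%), and from 46.3% to 56.5% for term against 130 days. Signal over background limits dim probes, which bear the changes given as bounds. Except where stated, the cause was not tested.

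For term against 130 days, 1121 genes became 460 with normexp, 2420 with the 2 groups alone, 3212 with array weights, 2244 with slide as a block on the fetal arrays alone and 1702 with scan date as a block. Leaving out each array gave 644 (without 130-day fetus 3) to 1406, with 671 and 723 without 130-day fetuses 1 and 4. For lamb against term, 5149 became 2835 with normexp and 977 with scan date as a block, and 4792 to 5710 with 1 array left out. For lamb against 130 days, 4972 became 946 with scan date as a block, and 4381 to 5268 with 1 array left out. The contrast of intervals, 3211, became 1135 with normexp, 4898 with array weights and 1190 with scan date as a block, and 2686 to 3808 with 1 array left out. Genes called in both intervals, 532, became 176 with normexp, 994 with 2 groups, 1569 with array weights, 921 with slide as a block (fetal arrays alone for the first interval) and 125 with scan date as a block, and 307 (without 130-day fetus 3) to 709 with 1 array left out (327 without 130-day fetus 1).

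Lists called for term against 130 days were 0 with an estimated correlation (7 otherwise), and 6 to 9 with 1 array left out. For lamb against term 0 lists became 1 with normexp, 1 with the replicate block, 8 with fry and 2 without the lambs of slide 7, and 0 to 1 with 1 array left out, the 1 arising without 130-day fetus 3, term fetus 7 or lambs 4, 6 or 7. For lamb against 130 days 1 list became 2 with normexp, 0 with an estimated correlation and 3 with fry, and stayed 1 to 1 with 1 array left out.

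These directions reversed. With normexp the changes were 0.23 for IL1A (term against 130 days), 0.04 for ISL1, 0.10 for AHSP, 0.10 for MYOD1 and 0.19 for NR3C1 (lamb against term), and 0.31 for LTF and 0.48 for NR3C1 (lamb against 130 days). EGR1 was 0.54 with the mean of its probes, one of which moves the other way. NR3C1 for lamb against 130 days was 0.20 with quantile normalisation, 0.22 with array weights, 0.13 with the authors' values, 0.03 without lamb 1, 0.03 without lamb 4 (lowest with 1 array left out -0.35, without lamb 8), 0.21 without slide 5 and 0.06 without slide 6. For lamb against term it was 0 with array weights and 0.01 without slide 5. Among lists none of which was called, the adjusted p in the reversed direction was, for term against 130 days, 0.87 for ribosome and hypoxia and 0.692 for immediate early genes with normexp, 0.1 for ribosome with quantile normalisation, and for immediate early genes 0.837 with fry and 0.839 with the GC correction. For lamb against 130 days it was 0.796 for glycolysis, oxidative phosphorylation and insulin-like growth factor and 0.92 for hypoxia with normexp, 0.892 for hypoxia with quantile normalisation, 0.985 for antioxidant genes with slide as a block, 0.945 for hormone signalling with the replicate block, and with fry 0.517 for hormone signalling and 0.771 for angiogenic and adipocyte genes. For lamb against term it was 0.918 for glycolysis with slide as a block.

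Groups share replicate numbers, but samples of 1 number did not deviate together (correlations of -0.169 to 0.061 between term and 130 days, 0 of 6 over 0.1), and 0 samples correlated best with their own number there. Between 130 days and lamb the range was -0.159 to 0.106, with 1 pair over 0.1, and between term and lamb -0.141 to 0.056. With the replicate block 742 genes passed for term against 130 days, and NR3C1 was -0.02.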

Other observations

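Some genes outside the lists large enough to test also differed between the groups, where for lambs against fetuses age cannot be told apart from slides and scan dates. Between 130 days and term the sarcomere genes CRYAB, a chaperone (0.77 ± 0.21, limma adjusted p = 0.0214, 8 of 8 term arrays), and TPM1, a tropomyosin (0.67 ± 0.12, adjusted p = 0.00228, 8 of 8), rose, as did the mitochondrial ADP/ATP carrier SLC25A4 (0.86 ± 0.17, adjusted p = 0.00336, 8 of 8) and myoglobin, MB (0.48 ± 0.12, adjusted p = 0.018, 7 of 8). The calls of TPM1 (0.27, adjusted p = 0.0525) and MB (0.09, adjusted p = 0.731) ended with quantile normalisation and with the authors' values, those of CRYAB (0.71, adjusted p = 0.0626) and MB with normexp, and that of CRYAB without 130-day fetus 3 (0.71, adjusted p = 0.0619) or 130-day fetus 1. The replicate block ended those of CRYAB (0.67, adjusted p = 0.0676) and MB (0.45, adjusted p = 0.0664), and the fit of slides 1 to 3 alone that of MB (0.46, adjusted p = 0.0664). Between term and lamb the potassium channel KCNK3 fell by 1.92 ± 0.16 (adjusted p = 1.91e-08, 8 of 8 lambs), the cardiac progenitor factor ISL1 by 1.59 ± 0.32 (adjusted p = 0.000419, 8 of 8), the transcription factor HAND1 by 0.76 ± 0.12 (adjusted p = 4.3e-05, 8 of 8) and neuropeptide Y, NPY, by 1.56 ± 0.22 (adjusted p = 6.92e-06, 8 of 8, with -1.77 to -0.79 over all alternatives). With normexp the calls of KCNK3 (-0.45), ISL1 (0.04) and HAND1 (-0.28) ended, and with scan date as a random block that of ISL1 (adjusted p = 0.107).

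The tests of the next pattern were all chosen after the result was seen. All 4 measured cathelicidin genes were lower in lambs than at 130 days (median -5.94, 8 of 8 lambs for each). Fewer leukocytes of every kind would lower their markers alike, but 0 of 11 leukocyte markers reached below -3 (lowest bound of their 95% intervals -1.89, median -0.48), which argues against it. With normexp 4 of 4 cathelicidin genes stayed called, which argues against background correction as the whole cause. Their changes went from -6.95 to -3.60 for CATHL1B, -6.18 to -3.09 for CATHL3, -5.69 to -3.14 for BAC5 and -3.02 to -1.36 for SC5. The signal used, its background correction and the offset may thus set much of the size. For the part between 130 days and term, slides are argued against too, as 3 of 4 were called with slide as a block in a fit of the fetal arrays alone (CATHL1B -3.30 ± 0.63, CATHL3 -2.91 ± 0.73, BAC5 -2.79 ± 0.70). Without the block and with the lambs also in the fit, these 3 changes did not pass in limma (-2.55, -2.23 and -2.03, with adjusted p = 0.0694, 0.176 and 0.161). For the part between term and lamb 0 of 4 were called by limma with scan date as a random block (CATHL1B -4.54, adjusted p = 0.0927), so slides and dates cannot be told apart from age there, and fewer developing myeloid cells, which may carry these genes, stays an untested explanation.

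Bright genes held very low values on a few lamb arrays. Of 500 genes with a median above 4, 8 had at least 1 array more than 5 below that median, 13 values in all. All 13 lay on lamb arrays, 7 on lamb 1, 4 on lamb 8 and 1 each on lambs 3 and 5, and 5 of the 8 genes had such a value on more than 1 lamb.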
